A study of Mus musculus with 6 samples.

How the data were processed

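Liver RNA of 6 mice, 2 each on the HFC diet alone, with lovastatin or with fenofibrate, was hybridised on 2-colour arrays against pooled RNA of 6 chow-fed mice, with 0.5 µg of total RNA per labelling by a linear amplification kit per the labels' protocols. The series' design text describes 24 mice aged 7 weeks in 4 arms of 6, and the other mice were not analysed here. Groups came from the sample titles. The treatment text of the lovastatin samples names fenofibrate at 100 mg/kg, while their titles and source names say lovastatin, and the titles were followed. Replicates are separate mice per the labels.

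The deposited table holds 1 value per spot and array, made by the authors, which was read as a log2 ratio. The scanner software, background correction and normalization are not given in the sources used here. Array medians lay between -0.01 and 0.03, and whether the authors centred the arrays is not stated. Repeated unnamed control spots hold the same value within an array, and how that value was formed is not stated either. The log base is not given: a control value of -9.71 is beyond the range that 16-bit signals allow on a log10 scale (4.82), so base 2 was taken by convention. No intensities were used here, so dim probes were not filtered, and the number of arrays limits the precision.

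Of 22575 spots, 726 had no value on any array and 561 repeated unnamed control spots were left out, which left 21288 probes. The platform annotation gives 1 gene symbol for 18658 probes, several for 30 and none for 3887 spots. By Entrez number 18445 probes matched the gene table, and 0 symbols were updated. Probes of a gene were averaged on the log2 scale (1247 genes had more than 1 probe), giving 16887 genes. With 2630 unnamed probes kept single and not named, 19517 features were tested.

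Group means were fitted with limma 3.58.1 and statmod 1.5.0 in R 4.3.3. All 3 groups shared an estimate of the spread (3 residual degrees of freedom, prior 2.63), and p-values were adjusted by Benjamini-Hochberg over all features with a threshold of 0.05. The ratio against 0 tests a group against the pool and leaves out the spread between chow mice. It also holds any gene-specific dye effect, since the mouse has the same dye on all arrays of a group. The dye-balanced contrast weights HFC and lovastatin by 0.25 each and fenofibrate by 0.5. The median 95% interval reached 0.656 on either side for HFC against the pool, 0.402 for the dye-balanced contrast and 0.928 for fenofibrate against HFC. Gene lists, 27 in number, were tested with limma camera at a preset correlation of 0.01, adjusted over 189 tests (27 lists and 7 comparisons), and again with an estimated correlation. Negative estimates were set to 0, which is less strict than the preset 0.01. With the displaced blocks put back, the estimate was 0 for the amino acid, growth hormone, interferon and oxidative stress lists, among others. A call kept at an estimate of 0 is no stricter check. Calls given as deposited use estimates from that fit, which may differ, as for the amino acid list, whose adjusted p rose there. The mean, median and test direction differed in sign in 19 of the 189 tests, 0 of which passed.

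Lists, comparisons, the first set of other settings and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, up to 10 largest rises and 10 largest falls among genes past the threshold with the same sign on every array (or with the arrays of the 2 groups not overlapping), the 5 genes with the smallest p where fewer than 3 pass, up to 4 members with the smallest p of each list described, and a fixed set of genes where measured, which gave Sqle, Cyp7a1, Cyp4a10, Cyp4a14, Pdk4, Scd1, Fasn and Abcg5. Genes given as passing with the displaced blocks put back come from the same rule in that fit. Data were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

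The fit was tested on simulated data with 200 changed genes among 19517 features. Of changes of 1, 2 and 4 log2 units it recovered 1.33%, 42.7% and 90% for HFC, 1.33%, 28% and 86% for lovastatin, 0%, 40% and 82% for fenofibrate against the pool, and 30.7%, 85.3% and 98% for the dye-balanced contrast. It recovered 0%, 1.33% and 58% for lovastatin against HFC, 0%, 0% and 60% for fenofibrate against HFC, and 0%, 0% and 54% for fenofibrate against lovastatin. Of 20 simulated lists shifted by 1 log2 unit, camera gave 20 an unadjusted p under 0.05, and of 20 unchanged lists 0. The simulated genes were independent, and a gene had the same spread on every array. The real arrays differed in spread (SD 0.419 to 1.09) and 1 holds displaced blocks, so these rates do not carry over to the real data.

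Other settings fixed with them included median centring, quantile normalization, single probes, removal of the noisiest 10% of features, a robust prior, a replicate block, fits on the compared arrays alone, leaving out each array, and turning the sign of the fenofibrate arrays. Alternatives chosen after seeing the data were the displaced blocks of HFC replicate 2 put back or left out, and the arrays of wide spread left out.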

Results

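Liver RNA of 6 C57BL/6 mice was measured on 2-colour oligonucleotide arrays, 1 mouse per array, against a common reference. All 6 mice were kept on the HFC diet, called a high-fat diet in the sample names, for 12 days. From day 5 the study dosed its HFC-fed mice with vehicle, lovastatin at 30 mg/kg or fenofibrate at 100 mg/kg, and each arm has 2 arrays here. Lovastatin inhibits cholesterol synthesis, and fenofibrate activates PPARα, a nuclear receptor that controls fatty acid oxidation. The lovastatin group is taken from the sample titles, although the treatment text of these samples names fenofibrate. The reference was pooled liver RNA of 6 chow-fed mice. The mouse was labelled with Cy5 on the HFC and lovastatin arrays and with Cy3 on the fenofibrate arrays, so dye and fenofibrate cannot be separated gene by gene.

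Values are ratios on a log scale, taken as log2 and read as mouse over pool. That direction is likely rather than stated, since the labels list the mouse as the first channel on every array. A repeated unnamed control lay between -9.71 and -4.20 on the 4 arrays with the mouse in Cy5 and at 4.83 and 4.95 on the other 2. These values bear on whether the 2 dye orientations are read alike. They do not tell mouse over pool from pool over mouse. The size of these values excludes base 10 and leaves base e open.

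The arrays differed in spread and in how well replicates matched. The SD over all probes was 0.419 for HFC replicate 1, 0.725 for HFC replicate 2, 1.09 for lovastatin replicate 1, 0.420 for lovastatin replicate 2, and 0.469 and 0.570 for the fenofibrate arrays. Across features, which are not independent replicates, the correlation of the 2 replicates was 0.0888 for HFC, 0.189 for lovastatin and 0.402 for fenofibrate. In 4 of 8 blocks of array columns, HFC replicate 2 had almost no correlation with the mean of the other arrays (-0.0374 to 0.0232). Lovastatin replicate 1, the widest array, was left out of that mean. Rotating the values of each such block along the array rows raised the correlation to between 0.299 and 0.315, and no other rotation exceeded 0.0438. None of the 40 blocks on the other arrays did this. These displaced blocks hold 10703 of the 21288 probes used (50.3%). Results are given for the values as deposited. Results with the blocks put back or left out, alternatives chosen after seeing the data, stand beside some of them, and many list results are given as deposited only.

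**Figure D1:**
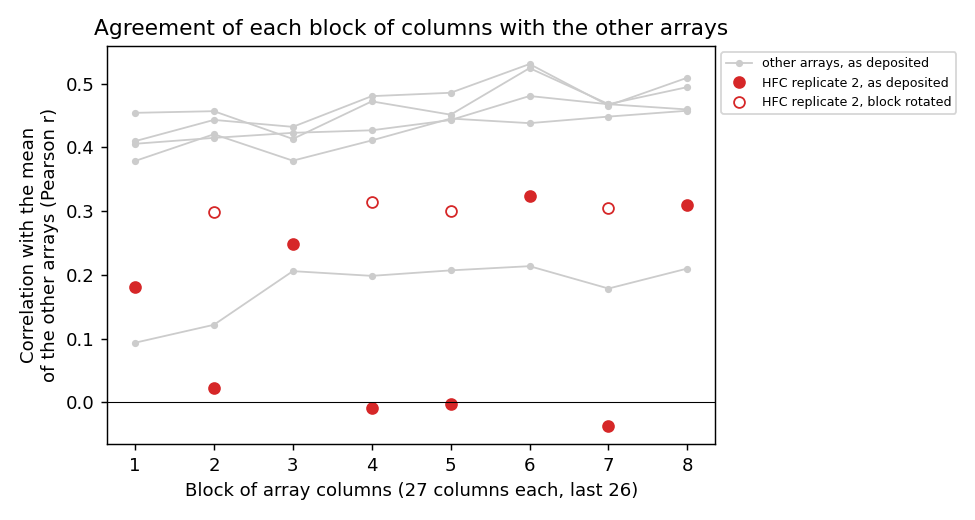
Pearson correlation of each of 8 blocks of array columns with the mean of the other arrays, for HFC replicate 2 (filled points as deposited, open points after rotation) and for the other 5 arrays (grey). Every mean leaves out HFC replicate 2 and lovastatin replicate 1. Blocks 2, 4, 5 and 7 of HFC replicate 2 lie near 0 as deposited and at 0.299 to 0.315 after rotation.

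The broadest question was what the livers of HFC-fed mice shared against the chow pool, whatever the drug, with both dye orientations given equal weight. Genes of cholesterol synthesis fell, among them Sqle, squalene epoxidase (-3.81, SE 0.138), Fdps, farnesyl diphosphate synthase (-3.48, SE 0.173), and Pmvk, phosphomevalonate kinase (-2.15, SE 0.173). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.09, SE 0.137), and Cyp8b1, the sterol hydroxylase needed for cholic acid (-2.85, SE 0.153), also fell. Genes of fatty acid handling rose, among them Acot1, an acyl-CoA thioesterase (2.89, SE 0.175), Fabp2, a fatty acid binding protein (2.01, SE 0.120), and the fatty acid omega-hydroxylases Cyp4a14 (2.12, SE 0.173) and Cyp4a31 (1.92, SE 0.134). Each of these 9 genes lay on the same side of 0 on all 6 arrays. Sizes differed by group, with Cyp4a14 at 0.84 in HFC (0.93 put back), 2.12 in lovastatin and 2.76 in fenofibrate mice.

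The largest fall among named genes was that of Sult3a1, a sulfotransferase (-5.38, SE 0.235, limma adjusted p = 0.00685). Rdh11, a retinol dehydrogenase, fell (-2.61), as did Dio1, a thyroid hormone deiodinase (-2.36), Sult1e1, the oestrogen sulfotransferase (-2.30), Tafa2 (-2.64) and Nfe2 (-2.41). Among the rises were Krt23, a keratin (2.29), Gstm1, a glutathione transferase (2.13), Unc79 (1.94), Lpl, lipoprotein lipase (1.86), Prom1 (1.83) and Cyp3a25 (1.75), with limma adjusted p from 0.0213 to 0.0432. Krt23, Cyp4a14, Cyp4a31 and Fasn lie in displaced blocks and were at 2.52, 2.14, 1.91 and -1.68 put back. Abcg5, which exports sterols into bile, was at 1.30 (limma adjusted p = 0.0432) and Cyp4a10 at 1.29 (limma adjusted p = 0.0425). In HFC, lovastatin and fenofibrate mice Abcg5 was at 1.30, 1.26 and 1.32, and Cyp4a10 at 0.52, 0.80 and 1.93. Scd1 (0.47, limma adjusted p = 0.518), Pdk4 (0.063, limma adjusted p = 0.919) and Fasn (-1.65, limma adjusted p = 0.172) did not pass, and Apoa4 was not measured here.

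Of 17 measured cholesterol synthesis genes, 17 lay below 0, 4 passed over all features and 17 passed adjusted over the list alone. The list mean was -2.30 (limma camera adjusted p = 4.17e-25, and adjusted p = 0.00378 with an estimated correlation). The fourth gene to pass was Ebp (-1.20). In Idi1 and Msmo1, sterol pathway enzymes in displaced blocks, HFC replicate 2 was at 0.07 and -0.02 as deposited and at -4.27 and -4.13 put back, while the other 5 arrays lay from -4.83 to -4.08 and from -4.08 to -3.56. With the blocks put back Idi1 (-4.55), Msmo1 (-3.85) and Dhcr7 (-3.05) passed, at limma adjusted p = 0.00221, 0.00221 and 0.00429. Insig2, a regulator of sterol sensing, rose (1.32), while the list of sterol regulation and uptake genes it belongs to had a mean of -0.19 and did not pass (limma camera adjusted p = 0.362).

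**Figure D2:**
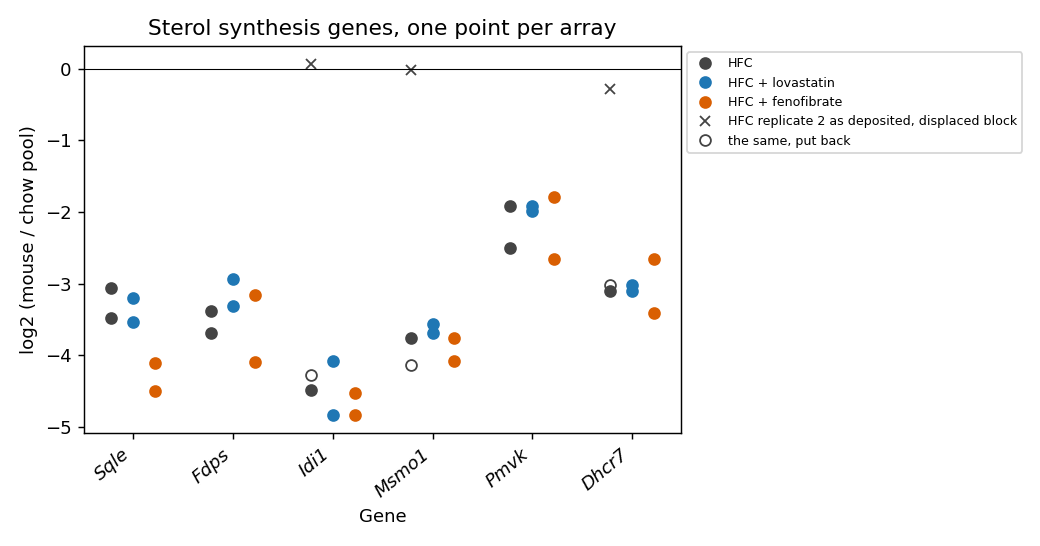
Log2 ratio of mouse to chow pool for 6 cholesterol synthesis genes, each point an array. Crosses are HFC replicate 2 as deposited where its probe lies in a displaced block (0.07 for Idi1), and open circles the same value put back (-4.27 for Idi1).

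Of 25 measured genes of omega oxidation and fatty acid handling, 5 were higher and 1 was lower past the threshold, and 14 were higher and 3 lower adjusted over the list alone. Fabp5, another fatty acid binding protein, was the member that fell (-1.33). The list mean was 0.61 (limma camera adjusted p = 6.00e-07, and adjusted p = 0.00378 with an estimated correlation). Its median was highest on the fenofibrate arrays (0.84 and 1.2). It was 0.49 and 0.03 on the HFC arrays, the latter 0.205 put back, and 0.32 and 0.36 on the lovastatin arrays. Of 14 oxidative stress genes, Ephx1, epoxide hydrolase (1.36), and Gclc, of glutathione synthesis (1.40), rose, and 3 passed adjusted over the list alone. That list had a mean of 0.40 (limma camera adjusted p = 1.45e-05, and adjusted p = 1.57e-05 with an estimated correlation). Of 27 xenobiotic metabolism genes, Cyp3a25 and Gstm1 rose and Cyp2c40 fell (-1.24), and 13 were higher and 3 lower adjusted over the list alone. The mean of this list was 0.52 (limma camera adjusted p = 0.00189, and adjusted p = 0.265 with an estimated correlation). In lovastatin mice alone the oxidative stress (mean 0.27, limma camera adjusted p = 0.0656) and xenobiotic lists (mean 0.36, limma camera adjusted p = 0.205) did not pass.

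Amino acid and urea cycle genes were lower as a group (mean -0.53, 16 of 17 below 0, limma camera adjusted p = 7.03e-08, and adjusted p = 2.97e-05 with an estimated correlation). Got1, aspartate aminotransferase, was the member that passed (-1.47), and 8 passed adjusted over the list alone. Growth hormone regulated genes had a mean of -0.91 (limma camera adjusted p = 1.90e-05, and adjusted p = 4.55e-05 with an estimated correlation), with Sult3a1 past the threshold and 5 of 12 lower adjusted over the list alone. Sult3a1, at -5.38, weighs on this mean. Put back, the list median was -0.43, with 9 of 12 below 0. Interferon response genes had a mean of -0.32 (13 of 18 below 0, limma camera adjusted p = 2.55e-05, and adjusted p = 1.81e-05 with an estimated correlation), with 0 past the threshold and 8 adjusted over the list alone. This call came from the fenofibrate arrays (mean -0.57), as the list did not pass in HFC (mean -0.078, limma camera adjusted p = 0.261) or lovastatin mice (mean -0.046, limma camera adjusted p = 0.416) against the pool. Lymphocyte markers were lower too (mean -0.17, limma camera adjusted p = 0.0225, and adjusted p = 0.281 with an estimated correlation), a call lost without HFC replicate 1 (limma camera adjusted p = 0.124), lovastatin replicate 2 (0.0557) or fenofibrate replicate 1 (0.0634). They did not pass in HFC (mean -0.0088, limma camera adjusted p = 0.731) or lovastatin mice (mean -0.15, limma camera adjusted p = 0.178). Acly, ATP citrate lyase, was the fatty acid synthesis gene that fell (-1.71), with 9 of 24 lower adjusted over the list alone, and the list mean was -0.55 (limma camera adjusted p = 4.78e-06, and adjusted p = 0.0515 with an estimated correlation). G6pc, glucose-6-phosphatase, fell (-1.76) in a gluconeogenesis and glycolysis list with a mean of -0.50 (limma camera adjusted p = 0.00189, and adjusted p = 0.00274 with an estimated correlation). Of 22 bile acid genes Cyp7a1 and Cyp8b1 fell, 4 were higher and 5 lower adjusted over the list alone, and the mean was -0.31 (limma camera adjusted p = 0.0484, and adjusted p = 0.108 with an estimated correlation). This call was lost without HFC replicate 1 (limma camera adjusted p = 0.0766), HFC replicate 2 (0.0804), lovastatin replicate 2 (0.0860) or fenofibrate replicate 1 (0.206), and the list did not pass in HFC (mean -0.15, limma camera adjusted p = 0.327) or lovastatin mice (mean -0.32, limma camera adjusted p = 0.167).

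By limma, 67 of 19459 features passed, 23 higher and 44 lower, 60 of them named genes. With the displaced blocks put back 189 passed (65 higher, 124 lower), including all 67, and with them left out 110 passed. The count was 0 without HFC replicate 1, fenofibrate replicate 1 or fenofibrate replicate 2, 25 without HFC replicate 2, 383 without lovastatin replicate 2, and 0 with the sign of the fenofibrate arrays turned.

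The comparison of HFC mice with the pool asks what the diet did without a drug. The mouse was in Cy5 on both arrays, so the values also hold any gene-specific dye effect. No gene passed. Among the genes of smallest p, Sqle had a mean of -3.27 ± 0.297 (SD, n = 2), Fdps -3.54 ± 0.219, Sult3a1 -4.21 ± 0.997, Dio1 -2.41 ± 0.0778 and Rdh11 -2.42 ± 0.233, each at limma adjusted p = 0.155. Cyp7a1 was at -1.54 and Abcg5 at 1.30 (limma adjusted p = 0.359 and 0.521). Cyp4a14 (0.84, 0.93 put back), Cyp4a10 (0.52), Scd1 (0.64), Fasn (-1.08, -1.18 put back) and Pdk4 (0.00) had limma adjusted p of 0.936 or higher. With the blocks put back, Idi1 (-4.38) and Msmo1 (-3.94) passed at limma adjusted p = 0.0415, together with an unnamed probe.

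Cholesterol synthesis genes were lower as a group (mean -1.55 as deposited and -2.35 put back, 17 of 17 below 0, limma camera adjusted p = 4.37e-15, and adjusted p = 0.0392 with an estimated correlation), with 0 past the threshold over all features and 6 adjusted over the list alone. Growth hormone regulated genes were lower (mean -0.79, 10 of 12 below 0, limma camera adjusted p = 4.78e-06) and oxidative stress genes higher (mean 0.38, 11 of 14 above 0, limma camera adjusted p = 0.000504). Both calls held with an estimated correlation. With the blocks put back the estimate was 0 for both lists, and so no stricter than the preset in that fit. In each of these lists 3 members passed adjusted over the list alone and 0 over all features. Amino acid and urea cycle genes had a mean of -0.34 (limma camera adjusted p = 0.000515, and adjusted p = 0.0111 with an estimated correlation). Without HFC replicate 1, which leaves the array with the displaced blocks, the mean was -0.16. Those blocks hold 10 of the 17 members, and with them put back the mean was -0.51 (limma camera adjusted p = 7.98e-08). Xenobiotic metabolism genes had a mean of 0.60 (limma camera adjusted p = 8.21e-05, and adjusted p = 0.139 with an estimated correlation). With the blocks put back the mean of this list was 0.70 (limma camera adjusted p = 0.00045), and without HFC replicate 1 it was 0.43. Fatty acid synthesis genes were lower (mean -0.43, 20 of 24 below 0, limma camera adjusted p = 1.79e-05, and adjusted p = 0.0662 with an estimated correlation). Cyp3a25 (2.03), Gstm1 (2.70), Cyp3a11 (2.02) and Gstm2 (1.65) had the smallest p of the xenobiotic genes, 0 passing over all features and 6 higher and 1 lower adjusted over the list alone.

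By limma, 0 of 19517 features passed and 946 had an unadjusted p under 0.05. The count was 3 with the displaced blocks put back, 0 with them left out, and 86 without HFC replicate 1, which leaves the displaced array as the HFC sample.

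In the lovastatin mice against the pool, which asks the same of diet and lovastatin together, no gene passed. These arrays also have the mouse in Cy5 only, so their values hold any dye effect too. Sqle (-3.37 ± 0.240, SD, n = 2), Sult3a1 (-5.17 ± 0.410), Rdh11 (-2.94 ± 0.389), Dio1 (-2.23 ± 0.0283) and Cyp8b1 (-2.80 ± 0.537) had the smallest p, at limma adjusted p from 0.124 to 0.161. Cyp7a1 was at -2.06, Cyp4a14 at 2.12, Cyp4a10 at 0.80, Abcg5 at 1.26, Fasn at -1.48, Scd1 at -0.015 and Pdk4 at -0.040, at limma adjusted p from 0.178 to 0.986. Cholesterol synthesis genes were lower as a group (mean -2.31, 17 of 17 below 0, limma camera adjusted p = 3.25e-14, and adjusted p = 0.0461 with an estimated correlation), with 0 past the threshold over all features and 16 adjusted over the list alone. Growth hormone regulated genes (mean -0.93, 5 of 12 lower adjusted over the list alone, limma camera adjusted p = 0.00189, and adjusted p = 0.00378 with an estimated correlation) and amino acid and urea cycle genes (mean -0.47, 17 of 17 below 0, limma camera adjusted p = 0.000504, and adjusted p = 0.0111 with an estimated correlation) were lower too. Without lovastatin replicate 2 these had limma camera adjusted p = 0.0994 and 0.105. Got1 (-1.15) and Ass1 (-0.95), of the urea cycle, were not past the threshold. Kupffer cell and macrophage markers were higher (mean 0.32, 16 of 19 above 0, limma camera adjusted p = 0.0173, and adjusted p = 0.128 with an estimated correlation), and had a mean of 0.095 without lovastatin replicate 1 (limma camera adjusted p = 0.296).

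By limma, 0 of 19501 features passed and 2261 had an unadjusted p under 0.05. With the blocks put back Idi1 (-4.46) and Msmo1 (-3.62) passed, both at limma adjusted p = 0.0376, with the blocks left out the count was 0, and without lovastatin replicate 2, which leaves the widest array as the lovastatin sample, it was 3139.

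In the fenofibrate mice against the pool, 2 genes of fatty acid handling rose and 2 of cholesterol synthesis fell. The mouse was in Cy3 on these arrays, so these values also hold any gene-specific dye effect. Acot1 rose (3.91 ± 0.205, SD, n = 2), as did Cyp4a31 (2.90 ± 0.156), and Sult3a1 (-6.07 ± 0.382), Sqle (-4.30 ± 0.276), Fdps (-3.63 ± 0.658) and Dio1 (-2.41 ± 0.0495) fell, each at limma adjusted p = 0.0479. Fabp2 (2.42, limma adjusted p = 0.0532), Cyp4a14 (2.76, 0.121), Cyp4a10 (1.93, 0.131), Cyp7a1 (-2.39, 0.0828), Abcg5 (1.32, 0.253), Fasn (-2.03, 0.493), Scd1 (0.64, 0.823) and Pdk4 (0.15) did not pass. With the blocks put back Krt23 (3.09), Spc25 (2.55), Cyp4a12a (1.88), Idi1 (-4.68), Mup5, a major urinary protein (-4.03), Msmo1 (-3.92), Lrtm1 (-3.85), Hmgcs1 (-3.23), Dhcr7 (-3.04) and Cyp8b1 (-2.95) also passed, as did Cyp4a14, Fabp2 and Cyp7a1.

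Of 25 genes of omega oxidation and fatty acid handling 2 passed, and 12 were higher and 2 lower adjusted over the list alone (mean 0.90, limma camera adjusted p = 6.15e-09, and adjusted p = 0.000701 with an estimated correlation). Peroxisomal beta-oxidation genes were higher (mean 0.56, 14 of 16 above 0, limma camera adjusted p = 1.92e-06, and adjusted p = 0.0645 with an estimated correlation), with 7 past the threshold adjusted over the list alone and 0 over all features. Ehhadh, the peroxisomal bifunctional enzyme, was at 2.08 and Eci2, an enoyl-CoA isomerase, at 1.02. Mitochondrial fatty acid oxidation genes were higher (mean 0.45, 17 of 21 above 0, limma camera adjusted p = 2.04e-06, and adjusted p = 0.0515 with an estimated correlation), with 8 passing adjusted over the list alone and 0 over all features, Acadvl (1.29) and Hadhb (1.14) at the smallest p. Fatty acid synthesis genes were lower (mean -0.61, 16 of 24 below 0, 0 passing over all features and 3 adjusted over the list alone, limma camera adjusted p = 0.000205, and adjusted p = 0.119 with an estimated correlation). All 17 cholesterol synthesis genes lay below 0, 2 passed over all features and 17 adjusted over the list alone (mean -2.66, limma camera adjusted p = 4.17e-25, and adjusted p = 0.00378 with an estimated correlation). Interferon response genes were lower (mean -0.57, 17 of 18 below 0, 0 passing over all features and 7 adjusted over the list alone, limma camera adjusted p = 6.15e-09, and adjusted p = 1.41e-09 with an estimated correlation), with Psmb9 at -1.05 and Ifit1 at -1.21. Kupffer cell and macrophage markers were lower with them (mean -0.25, 14 of 19 below 0, limma camera adjusted p = 0.00135, and adjusted p = 0.0392 with an estimated correlation). Lymphocyte markers were lower too (mean -0.26, limma camera adjusted p = 0.0281, and adjusted p = 0.301 with an estimated correlation), a call lost without fenofibrate replicate 1 (limma camera adjusted p = 0.124) or replicate 2 (0.0638).

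By limma, 9 of 19470 features passed, 2 higher and 7 lower, 6 of them named genes, and 1423 had an unadjusted p under 0.05. The count was 32 with the displaced blocks put back, 0 with them left out, 0 without either HFC array or either fenofibrate array, and 7 without either lovastatin array, and every direction turns if the sign of the fenofibrate arrays is turned.

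**Figure D3:**
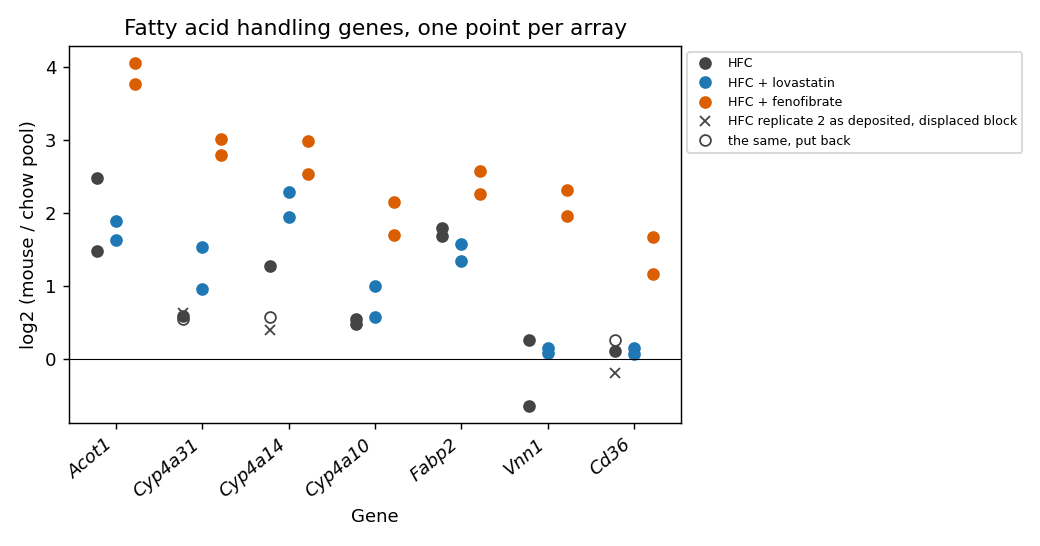
Log2 ratio of mouse to chow pool for 7 genes of fatty acid handling, each point an array, with the dyes reversed on the fenofibrate arrays. These arrays lie at 3.76 and 4.05 for Acot1 and at 1.96 and 2.31 for Vnn1, and the HFC arrays at 2.48 and 1.48 and at 0.26 and -0.63.

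Lovastatin against HFC, where dye and reference cancel, asks what lovastatin changed on the diet, and no gene passed. The smallest p belonged to Gse1 (-2.27, SE 0.306), Mt1, metallothionein 1 (-3.11, SE 0.461), Adcy2 (-1.88), Avil (-1.82) and Acsl6 (-1.73, -1.46 put back), all at limma adjusted p = 0.804. Mt1 was at -2.28 and -2.91 on the lovastatin arrays and at -0.05 and 1.08 on the HFC arrays, and Gse1 at -2.38 and -2.13 against -0.22 and 0.25. Sqle (-0.10), Cyp7a1 (-0.53), Cyp4a10 (0.28), Cyp4a14 (1.28), Pdk4 (-0.040), Scd1 (-0.66), Fasn (-0.40) and Abcg5 (-0.035) had limma adjusted p from 0.804 to 0.983.

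The cholesterol synthesis list was lower as deposited (mean -0.76, 15 of 17 below 0, limma camera adjusted p = 0.0259, and adjusted p = 0.601 with an estimated correlation), with 0 members past the threshold over all features or adjusted over the list alone. Of its members, 12 lie in the displaced blocks of HFC replicate 2, where their median on that array was 0.10 as deposited and -2.04 put back. With the blocks put back the list mean was 0.033 (limma camera adjusted p = 0.576), and without HFC replicate 2 it was 0.20 (limma camera adjusted p = 0.130), so the direction turned. Without HFC replicate 1, which leaves the array with the displaced blocks as the HFC sample, it was -1.72 and the call stayed, and without lovastatin replicate 2 it was -0.79 (limma camera adjusted p = 0.310). Kupffer cell and macrophage markers were higher (mean 0.32, 16 of 19 above 0, limma camera adjusted p = 0.0117, and adjusted p = 0.108 with an estimated correlation), with Marco at 0.97 and Cd68 at 0.56. Without lovastatin replicate 1, the widest array, the mean of these markers was 0.095 (limma camera adjusted p = 0.259), and without HFC replicate 1 it was 0.34 (limma camera adjusted p = 0.0751). Xenobiotic metabolism genes were lower (mean -0.24, 19 of 27 below 0, limma camera adjusted p = 0.0492, and adjusted p = 0.466 with an estimated correlation), with Gstm2 at -1.49, and lost the call without HFC replicate 1 (mean -0.068, limma camera adjusted p = 0.632), lovastatin replicate 1 (mean -0.0067, 0.511), lovastatin replicate 2 (mean -0.47, 0.0557) or fenofibrate replicate 2 (mean -0.24, 0.0505).

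By limma, 0 of 19501 features passed and 538 had an unadjusted p under 0.05, and the count was also 0 with the displaced blocks put back or left out. It was 59 without HFC replicate 1 and 1206 without lovastatin replicate 2, and the median 95% interval reached 0.932 on either side of the estimate.

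Fenofibrate against HFC asks what fenofibrate changed on the diet, with the dyes reversed between the groups. Genes of omega oxidation and fatty acid handling were higher as a group (mean 0.62, 18 of 25 above 0, limma camera adjusted p = 4.62e-06, and adjusted p = 0.00983 with an estimated correlation). None passed over all features, and 9 were higher and 2 lower adjusted over the list alone. Cyp4a31 (2.29, SE 0.310), Vnn1, pantetheinase (2.32, SE 0.379), Cyp4a14 (1.92, SE 0.398) and Cd36, a fatty acid translocase (1.46, SE 0.305), had the smallest p of the list, each at limma adjusted p = 0.999. Put back, Cyp4a31, Cyp4a14 and Cd36 were at 2.33, 1.83 and 1.23. Slc39a5 (2.05, 1.69 put back), Chst11 (2.10, 2.03 put back), Mro (-1.72, -1.12 put back) and Kif17 (4.22) were the other genes of smallest p. Kif17 rests on HFC replicate 2 alone, in a displaced block, and was at -0.22 put back. Sqle was at -1.03, Cyp7a1 at -0.86, Cyp4a10 at 1.41, Fasn at -0.95, Pdk4 at 0.15, Abcg5 at 0.020 and Scd1 at -0.0050.

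Peroxisomal beta-oxidation genes (mean 0.57, 14 of 16 above 0, limma camera adjusted p = 2.60e-06) and mitochondrial fatty acid oxidation genes (mean 0.41, 17 of 21 above 0, limma camera adjusted p = 9.77e-06) were higher, and both had adjusted p = 0.0662 with an estimated correlation. Abcd3 (1.37), Ehhadh (1.65, 1.21 put back), Acadvl (1.22, 1.29 put back) and Acadm (1.07) had the smallest p of these lists, in which 0 members passed over all features or adjusted over the list alone. Interferon response genes were lower (mean -0.49, 16 of 18 below 0, limma camera adjusted p = 1.21e-05, and adjusted p = 1.57e-05 with an estimated correlation), and Kupffer cell and macrophage markers were lower with them (mean -0.25, limma camera adjusted p = 0.0134, and adjusted p = 0.115 with an estimated correlation). The marker call was lost without HFC replicate 1 (limma camera adjusted p = 0.172), lovastatin replicate 2 (0.0535) or fenofibrate replicate 2 (0.139). Lipoprotein genes were lower (mean -0.45, 13 of 17 below 0, limma camera adjusted p = 0.000779, and adjusted p = 0.000701 with an estimated correlation), with Apoh at -1.52 (-1.18 put back), Apoe at -1.03 and Vldlr at 1.18. Put back, the mean of the lipoprotein list was -0.35 (limma camera adjusted p = 0.0009). The cholesterol synthesis list was lower as deposited (mean -1.11, limma camera adjusted p = 5.74e-06, and adjusted p = 0.265 with an estimated correlation), and had a mean of -0.32 put back (limma camera adjusted p = 0.0972) and of -0.15 without HFC replicate 2 (limma camera adjusted p = 0.368).

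By limma, 0 of 19470 features passed and 644 had an unadjusted p under 0.05, and the count was also 0 with the displaced blocks put back or left out. It was 60 without HFC replicate 1 and 29 with the sign of the fenofibrate arrays turned.

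Between the drugs, no gene passed in fenofibrate against lovastatin. The dyes are reversed between these groups too, so the differences also hold any gene-specific dye effect. Omega oxidation and fatty acid handling genes were higher with fenofibrate (mean 0.54, 18 of 25 above 0, 0 passing over all features and 4 adjusted over the list alone, limma camera adjusted p = 0.000439, and adjusted p = 0.0565 with an estimated correlation). This call was lost without lovastatin replicate 2 (mean 0.53, limma camera adjusted p = 0.0860). Cyp4a31 (1.65), Vnn1 (2.01), Acot1 (2.15) and Cd36 (1.31) had the smallest p of the list. Interferon response genes were lower (mean -0.53, 17 of 18 below 0, limma camera adjusted p = 0.000361, and adjusted p = 0.000285 with an estimated correlation), with Cxcl10 at -1.09 and Irf9 at -0.73. Kupffer cell and macrophage markers were lower with them (mean -0.57, 18 of 19 below 0, limma camera adjusted p = 1.21e-05, and adjusted p = 0.00314 with an estimated correlation), with Marco at -1.76 and C1qc at -0.91, and 0 members of either list passed over all features or adjusted over the list alone. The marker median was 0.29 on lovastatin replicate 1, the widest array, 0.1 on lovastatin replicate 2, and -0.24 and -0.33 on the fenofibrate arrays. Gse1 (2.46), Hoxa9 (2.58), Mro (-1.87), Ifit1bl2 (1.89) and Slc39a5 (1.87) had the smallest p of all genes, at limma adjusted p = 0.710. Sqle was at -0.93, Cyp7a1 at -0.33, Cyp4a10 at 1.13, Cyp4a14 at 0.65, Pdk4 at 0.19, Scd1 at 0.65, Fasn at -0.55 and Abcg5 at 0.055.

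By limma, 0 of 19459 features passed and 1120 had an unadjusted p under 0.05, and the count was also 0 with the displaced blocks put back or left out. It was 1523 without lovastatin replicate 2 and 19 with the sign of the fenofibrate arrays turned.

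The calls of HFC and of lovastatin against the pool shared 0 features as deposited, since limma called 0 in either, with 946 and 2261 at an unadjusted p under 0.05. Put back, both had Idi1 and Msmo1 as lower features, 2 shared against 0.000205 for independent lists and a mean of 0.02 in 50 simulations of unchanged groups with a shared pool. Across features, the HFC and lovastatin differences from the pool correlated at 0.210 as deposited and 0.315 put back, beside 0.247 in the simulations. The covariances were 0.0560 and 0.0761, beside 0.0866 simulated. The pool could not be split, so part of any excess may come from it. Both groups also have the mouse in Cy5, so a gene-specific dye effect may add to it.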

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

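Putting back or leaving out the displaced blocks, leaving out wide-spread arrays and the alternatives of the overlap were chosen only after the data were seen, and so were all list alternatives except the estimated correlation and named genes only. Most counts moved by over 1.5 times in some setting, with 2 arrays per group, and the cause was not tested unless stated. Removing the noisiest 10% of features selects on spread and so raises counts by construction. Where leaving out an array leaves a single one in a group, that sample is assumed to vary like the other groups. Signal over background could not be examined, since no intensities were used.

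For HFC against the pool (0 features called by limma, 946 at an unadjusted p under 0.05), 16 were called without the noisiest features, 3 with the blocks put back, 28 with them put back and lovastatin replicate 1 left out, and 0 to 86 leaving out each array. For lovastatin against the pool (0 by limma, 2261 at an unadjusted p under 0.05) the counts were 20, 2 with the blocks put back, and 0 to 3139 leaving out each array. For fenofibrate against the pool (9), the count was 0 with quantile normalization, 0 with single probes, 65 without the noisiest features, 1 with a robust prior, 0 on its own arrays alone, 32 with the blocks put back, 0 with them left out, 0 without both wide arrays, 76 with the blocks put back and lovastatin replicate 1 left out, and 0 to 7 leaving out each array. For the dye-balanced contrast (67), it was 25 with quantile normalization, 253 without the noisiest features, 0 with the fenofibrate sign turned, 189 with the blocks put back, 110 with them left out, 22 without both wide arrays, 260 with the blocks put back and lovastatin replicate 1 left out, 29 from HFC and fenofibrate arrays alone, and 0 to 383 leaving out each array. Of the 25 under quantile normalization 18 were among the 67.

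By limma the comparisons between groups called 0 features, with 538, 644 and 1120 at an unadjusted p under 0.05. Leaving out each array gave 0 to 1206 for lovastatin against HFC, 0 to 60 for fenofibrate against HFC and 0 to 1523 for fenofibrate against lovastatin. Turning the fenofibrate sign gave 29 and 19 in the last 2. Of 189 list tests 74 passed, 32 with an estimated correlation and 52 to 72 leaving out each array. With the fenofibrate sign turned 82 passed, of which 60 had passed before and 22 of those kept their direction. The overlap of HFC and lovastatin calls was 0 as deposited, 11 without the noisiest features and 2 with the blocks put back.

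The arrays carry shared sample numbers, and deviations of same-numbered arrays correlated at -0.00437, -0.0139 and 0.0311, so the numbers give no pairing. With a replicate block the count was 0 for fenofibrate against the pool and 12 for the dye-balanced contrast, and 0 in the other comparisons.

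Turning the sign of the fenofibrate arrays reverses them by construction. Against the pool Acot1 was then at -3.91, Cyp4a31 at -2.90, Sult3a1 at 6.07, Sqle at 4.30, Fdps at 3.63 and Dio1 at 2.41. In the dye-balanced contrast Acot1 was at -1.02, Krt23 at -0.80, Cyp4a14 at -0.64, Fabp2 at -0.41, Unc79 at -0.37, Cyp4a31 at -0.98, Lpl at -0.47, Cyp3a25 at -0.14, Cyp4a10 at -0.63 and Abcg5 at -0.019. There Sult3a1 was at 0.69, Sqle at 0.49, Fdps at 0.15, Cyp8b1 at 0.10, Tafa2 at 0.45, Nfe2 at 0.25, Dio1 at 0.044, Sult1e1 at 0.35, Pmvk at 0.074 and Cyp7a1 at 0.30. Against HFC Cyp4a31 was at -3.52, Sqle at 7.57 and Cyp7a1 at 3.93, and against lovastatin Sqle was at 7.67, Cyp7a1 at 4.45 and Cyp4a14 at -4.88.

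The cholesterol synthesis list in lovastatin against HFC reversed from -0.76 to 0.033 with the blocks put back and 0.12 with them left out, and leaving out each array it ranged from -1.72 to 0.20, as 12 of its 17 members lie in these blocks. Of all values under the alternatives, for results past the threshold or not, 58 of 1890 gene values and 98 of 2457 list values changed sign without a call.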

Other observations

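All tests of explanations reported here were chosen only after the results were seen. Acute phase genes were lower on the fenofibrate arrays as a group (mean -0.66 against the pool, 20 of 24 below 0, limma camera adjusted p = 6.08e-07, and adjusted p = 0.192 with an estimated correlation). Hamp, hepcidin, was at -2.31 and Fgb, fibrinogen beta, at -1.37, 0 members passed over all features and 4 adjusted over the list alone. Against HFC the list mean was -0.65 (limma camera adjusted p = 1.34e-05, and adjusted p = 0.271 with an estimated correlation), and -0.52 put back (limma camera adjusted p = 0.000365).

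Cell cycle genes were higher in the dye-balanced contrast (mean 0.64, 22 of 23 above 0, limma camera adjusted p = 6.43e-10, and adjusted p = 0.0195 with an estimated correlation), with Cdc20 at 1.60 (1.61 put back) and Ccnd1 at 1.16. None passed over all features and 8 did adjusted over the list alone. The median of the cell cycle list differed between arrays: 0.45 and 0.17 for HFC, -0.04 and 0.78 for lovastatin, and 0.57 and 1.09 for fenofibrate. Unfolded protein response genes were higher on the lovastatin arrays against the pool (mean 0.48, limma camera adjusted p = 0.0158, and adjusted p = 0.0662 with an estimated correlation), with Hyou1, an endoplasmic reticulum chaperone, at 2.43. That call was lost without lovastatin replicate 2 (mean 0.36, limma camera adjusted p = 0.486).

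In 4 column blocks, HFC replicate 2 did not follow the other arrays. Noise in these columns is argued against, since rotations found on odd array rows gave correlations of up to 0.316 on even rows, where noise would give none above 0.1. A different response of this mouse as the whole cause is argued against by the lowest of these correlations, 0.237, since a response belongs to a gene and not to a place on the array. A movement of values along the rows within these blocks may account for the pattern, as it needs these correlations. At which step values could have moved stays open.

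The omega oxidation list was higher on the fenofibrate arrays than on the HFC arrays. The plan named this list and the peroxisomal list as a check on the direction of the fenofibrate arrays. Their rise and that direction are therefore not independent. A gene-specific dye effect cannot be told apart from a response to fenofibrate, since 0 fenofibrate arrays have the mouse in the dye of the HFC arrays. A turned sign of the fenofibrate arrays is argued against by the cholesterol synthesis list, with 17 of 17 genes below 0 in both dye orientations. Its mean was -2.66 for fenofibrate, -2.31 for lovastatin, and -1.55 as deposited or -2.35 put back for HFC. The repeated control also argues against it (-9.71 to -4.20 with the mouse in Cy5, 4.83 and 4.95 with it in Cy3). The turned sign stays open, since under it a dye effect of that size could give the list 1 sign on all arrays. A control brighter in the pool would likewise give these control values. The covariance of the HFC and fenofibrate means, 0.0448 (correlation 0.236, beside 0.247 simulated for unchanged groups with a shared pool), did not exceed the 0.0560 of the HFC and lovastatin means, which share the dye, and decides neither.

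The treatment text of the lovastatin samples names fenofibrate, and whether these mice could have received it stays open. The omega oxidation list had a mean of 0.0802 in lovastatin minus HFC, and of 0.0164 with the displaced blocks, which hold 16 of its 25 members, put back. Its members went both ways and 0 passed by limma, with Cyp4a14 at 1.28 (1.19 put back), Vnn1 at 0.31, Cyp4a10 at 0.28 and Acot1 at -0.22, and the peroxisomal list mean was 0.13. The omega oxidation mean in fenofibrate minus HFC, 0.621 (0.557 put back), also holds the dye difference.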
